A study of Mus musculus with 9 samples.

How the data were processed

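RNA from mouse liver was sequenced in 9 libraries, 3 for each of 3 genotypes: p53+/- (p53-heterozygous), Tsc1fl/fl;Alb-Cre (Tsc1-deleted, with Cre recombinase driven by the albumin promoter, which acts in hepatocytes), and both together (double mutant). The labels give an age of 320 days for every library. The design text of the series counts 6 groups, and the 3 groups named here were analysed. The labels name TRIzol extraction, removal of ribosomal RNA and single reads of 50 cycles on a HiSeq, with 4 samples in each of 3 lanes. Which library ran in which lane is not given in the sources used here. One label calls the molecule polyA RNA, while the extraction text describes depletion of ribosomal RNA.

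The submitters' processing notes name cutadapt, STAR and StringTie, with no versions given in the sources used here, and the genome build mm9. Of the 52550 gene identifiers in each deposited table, 52403 matched GENCODE mouse release 21, which annotates a later build, so no coordinates are printed. The deposited tables hold 1 value per gene and library, and their unit was read from the values as FPKM (fragments per kilobase of gene length, scaled by the mapped reads) made by the authors. The header does not name it. The sum over genes of FPKM times annotated length came to 0.914 to 0.974 of the total that unit requires. The plain totals ranged from 446265 to 1075244, while TPM would give every library the same total. No counts were given. The FPKM step that 1 read makes in short single-transcript genes put the depth at about 10600000 to 18300000 reads per library.

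Values were used as deposited, as log2(FPKM + 1). The 12014 genes with at least 1 FPKM in at least 3 of the 9 libraries were tested with limma 3.58.1 in R 4.3.3, with an intensity trend and robust moderation of the variance. All 9 libraries were in 1 fit, and adjusted p values are Benjamini-Hochberg over the tested genes with a threshold of 0.05. The comparisons were double mutant minus Tsc1-deleted, double mutant minus p53-heterozygous, Tsc1-deleted minus p53-heterozygous, and the genes that passed with the same sign in the double mutant against both single mutants. Nothing in the labels pairs libraries across groups, and nothing says that the libraries of a group came from separate animals, so the p values measure the spread between these libraries. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

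Gene lists for liver functions, signalling programmes and cell types were fixed before the data were examined, and the 35 with at least 5 tested members were tested with camera from limma, two-sided, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 35 lists. Camera asks whether a list differs from all other genes, so a list can rank below the rest while its own median is above 0. The same test with a correlation estimated for each list, and the rotation test fry, were run beside it. Member counts are given over all genes and adjusted over the list alone.

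The rule for named genes was also fixed before the data were examined. It took Trp53, Tsc1 and Abcc4 whatever their values. Abcc4 was recalled from the study that made these data, so its values here are not independent evidence for it. For each comparison it took up to 10 rises and 10 falls with the largest change among genes that passed, had a mean of at least 2 FPKM in the higher group and did not overlap between groups. Where fewer than 5 genes passed, it took the 5 rises and 5 falls with the lowest p. From each list that passed or had at least 3 called members it took up to 4 called members with the largest change, and from lists that bear on cell type, sex or RNA quality the 3 members with the highest mean. Genes outside this rule are said to have been chosen after their values were seen.

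The settings tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-ratio rescaling, quantile normalization, limma without trend and robust steps, limma with array weights (whose estimation stopped before converging), only the 6 libraries compared, a block for the replicate number, and leaving out each library in turn. Added after the data were seen were rescaling to the same total of FPKM, rescaling every library to the same total over nuclear protein-coding genes (called nuclear rescaling), leaving out p53-heterozygous libraries 1 and 2, leaving out library 3 of that group with nuclear rescaling, the level of Xist as a covariate, and the 6 libraries compared with nuclear rescaling or with 1 left out. Overlaps between gene models were taken from GENCODE release 21.

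The test was also run on simulated log2 values, in which known genes had been shifted. They were drawn around the mean of each gene, with 1 spread per gene pooled over the groups. Depth was not simulated, nor the low nuclear share of p53-heterozygous libraries 1 and 2 or the larger spread of that group. Against the p53-heterozygous group the fit on 9 libraries recovered 1.5% and 62.1% of genes shifted by log2 changes of 1 and 4 for the double mutant, and 0% and 56.1% for the Tsc1-deleted group. For the double mutant against the Tsc1-deleted group the values were 0% and 68.2%, and 3% for a change of 2, with 3 false calls. The 2 comparisons against the p53-heterozygous group had 1 false call each. The fit on only the 6 libraries compared recovered 64.2% of genes shifted by 2 in that comparison, with 6 false calls. In the list test a list shifted by 1 was the only 1 of 35 called. Genes varied independently in that simulation, while the correlations estimated for the real lists ran from 0.108 to 0.966. It therefore cannot show how often camera at the preset correlation calls a list falsely in these data.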

Results

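The series title asks which transcripts could mark liver cancers that have lost both p53 and Tsc1 function. Liver RNA of p53-heterozygous, Tsc1-deleted and double-mutant mice, 3 libraries each, was compared. Trp53 encodes the tumour suppressor p53, and Tsc1 encodes a subunit of the complex that restrains the growth kinase mTORC1. Tsc1 stood at 0.15, 0.25 and 0.99 FPKM in the p53-heterozygous, 0.77, 0.92 and 0.95 FPKM in the Tsc1-deleted and 1.06, 1.14 and 1.04 FPKM in the double-mutant libraries. Trp53 stood at 0.53, 0.5 and 15.44 FPKM, at 7.07, 8.55 and 16.37 FPKM, and at 9.68, 5.88 and 6.9 FPKM. Whole-gene values do not separate the part of Tsc1 that Cre removes, and Cre does not act in every liver cell, so they do not check the labels. The p53-heterozygous livers differed among themselves more than any other group. Mitochondrial transcripts took 68.0% and 55.9% of the signal in p53-heterozygous libraries 1 and 2, 25.5% in library 3, 9.6% to 24.1% in the Tsc1-deleted libraries and 8.0% to 11.9% in the double mutant. Nuclear protein-coding genes were left with 7.4% and 6.6% in those first libraries, about 1000000 and 700000 reads, against 61.8% or more in the other 7 libraries. Library 3 of the p53-heterozygous group held 149.5 FPKM of Alb, the mRNA of serum albumin made by hepatocytes, against 2216 and 2375 FPKM in libraries 1 and 2 and 7971 or more in the other groups. It also held 265.3 FPKM of the collagen gene Col1a1, 699.0 FPKM of the macrophage lysozyme gene Lyz2 and 1774 FPKM of the actin gene Actb, each the highest of the 9 libraries. Across genes, log2 values correlated at 0.953 between p53-heterozygous libraries 1 and 2, at 0.598 and 0.572 between either and library 3, and at 0.919 or more within the other groups. Genes are not independent replicates in these correlations.

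**Figure D1:**
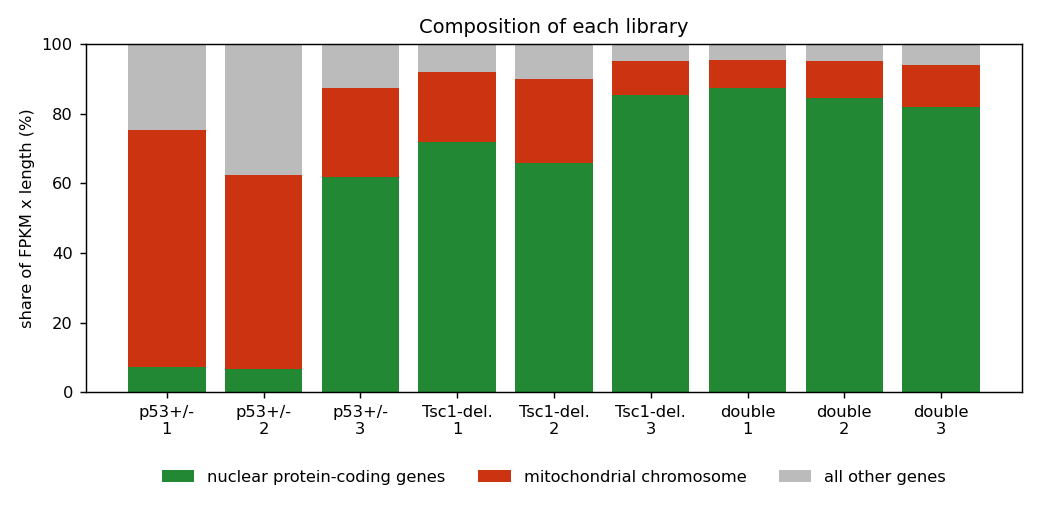
Share of FPKM times annotated gene length (%, vertical axis) held by nuclear protein-coding genes, the mitochondrial chromosome and all other genes in each of the 9 libraries (horizontal axis). Nuclear protein-coding genes hold 7.4% and 6.6% in p53-heterozygous libraries 1 and 2 and 61.8% to 87.3% elsewhere.

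**Figure D2:**
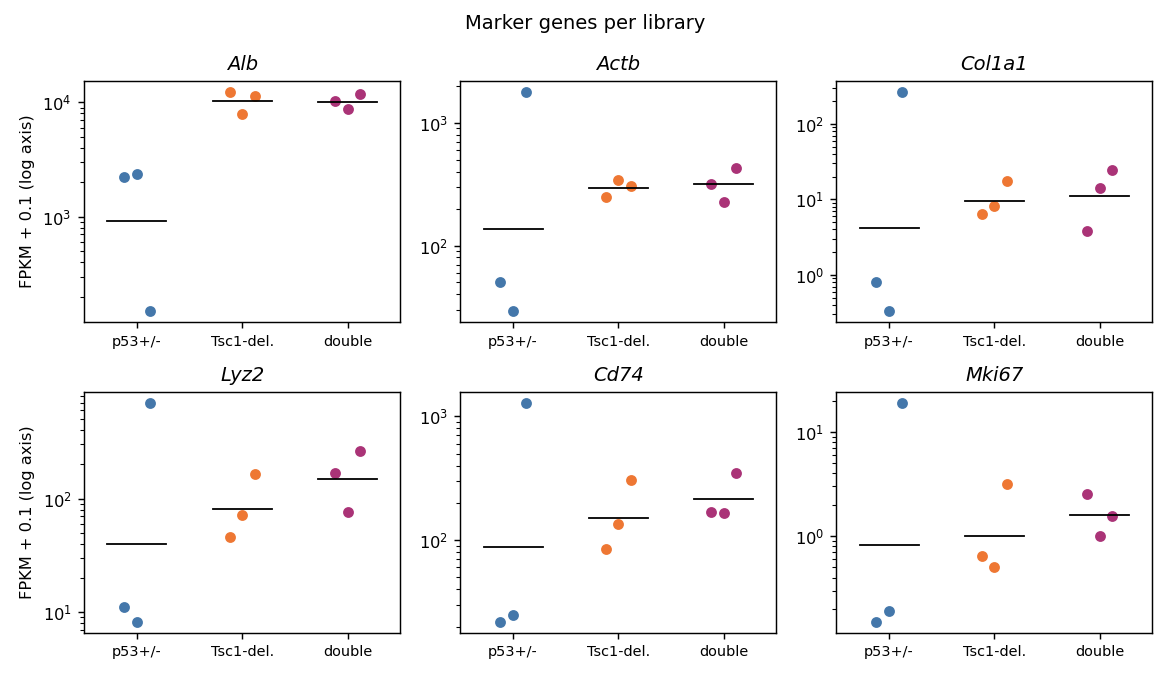
FPKM plus 0.1 on log axes for 6 marker genes. Each point is a library, and each line is the geometric mean of the 3 libraries of a group. Alb is lowest, at 149.5 FPKM, in the same p53-heterozygous library in which Actb, Col1a1, Lyz2, Cd74 and Mki67 are highest.

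The double mutant against the Tsc1-deleted liver asks what p53 heterozygosity adds where hepatocytes lack Tsc1. Double-mutant livers had more Slc39a5 (ENSMUSG00000039878, chromosome 10), which encodes a zinc transporter of the cell surface. It averaged 6.71 ± 0.661 FPKM against 0.173 ± 0.107 FPKM in Tsc1-deleted livers (SD, n = 3 each), a log2 change of 2.72 (SE 0.37, limma adjusted p = 0.0062). Adnp (ENSMUSG00000051149, chromosome 2), which encodes a chromatin-bound homeobox protein, stood at 11.09, 9.38 and 7.93 FPKM in the double mutant. In the Tsc1-deleted group it was listed at 0, 0 and 0.11 FPKM (limma adjusted p = 0.00151). Its model overlaps Gm20716 on the same strand, which stood at 0.29, 4.17 and 12.05 FPKM in the Tsc1-deleted and at 4.14, 0 and 0 FPKM in the double-mutant libraries. Hist2h2aa1 (ENSMUSG00000064220, chromosome 3), 1 of many genes for histone H2A, was listed at 0 in all 3 double-mutant libraries and at 33.36, 67.67 and 44.50 FPKM in the Tsc1-deleted ones (limma adjusted p = 0.029).

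These 3 genes were the ones that passed among 12014 tested, 2 higher and 1 lower in the double mutant, and 256 genes had an unadjusted p under 0.05. That is a smaller share than 0.05 of the genes tested. The fit on 9 libraries takes its spread per gene partly from the p53-heterozygous group, which is not part of this comparison. With only the 6 libraries compared, 3 genes passed and 1379 had an unadjusted p under 0.05 (limma). Slc39a5 and Adnp also passed after nuclear rescaling, and Hist2h2aa1 did not (adjusted p = 0.666, with a range over its alternatives of 2.65e-11 to 0.666). The log2 change of Hist2h2aa1 was then -5.21 against -5.57 as deposited, and it passed with nuclear rescaling on only the 6 libraries compared (adjusted p = 0.000589) or with p53-heterozygous library 3 out (adjusted p = 7.88e-05). Leaving out 1 library gave 6 genes without p53-heterozygous library 1, 5 without library 3 of that group, 5 without double-mutant library 2, and 0 without Tsc1-deleted library 2 (limma, 121 at an unadjusted p under 0.05). Within only the 6 libraries compared, leaving out Tsc1-deleted library 3 gave 1133 genes, 1035 higher and 98 lower, against 3 with all 6 and 4 to 13 without any other. The call for Slc39a5 ended without any 1 of the Tsc1-deleted libraries, at adjusted p = 0.0703, 0.161 and 0.0628. The log2 change of Slc39a5 was then 2.78, 2.64 and 2.73, and with only the 6 libraries compared it passed each time (adjusted p = 0.00408, 0.0144 and 0.00599). The call for Slc39a5 was also lost with a pseudocount of 0.1 (adjusted p = 0.0603), no filter (0.0519), a filter at 5 FPKM (0.163), limma without trend and robust steps (0.231) and the Xist covariate (0.0524), 8 of 31 alternatives in all, with a range of 1.51e-07 to 0.231. The call for Adnp ended without Tsc1-deleted library 2 (adjusted p = 0.0706) and with limma without trend and robust steps (0.0782), 2 of 31 alternatives. The call for Hist2h2aa1 ended without Tsc1-deleted library 2 or 3 or any 1 double-mutant library, at adjusted p between 0.103 and 0.308. It was also lost with a pseudocount of 5 (adjusted p = 0.0798), no filter (0.475), median-ratio rescaling (0.365) and quantile normalization (0.25). Limma without trend and robust steps (0.4) and the Xist covariate (0.0895) ended it too, 12 of 31 alternatives in all with nuclear rescaling.

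The other genes of the naming rule did not pass. The next lowest p values among higher genes were those of Casp9, an initiator caspase (0.368 ± 0.326 FPKM in Tsc1-deleted against 3.96 ± 0.513 FPKM in double-mutant livers, adjusted p = 0.275), Tbcel, a regulator of tubulin (adjusted p = 0.54), and Wif1, a secreted Wnt inhibitor (1.88 ± 0.7 against 20.03 ± 14.2 FPKM, adjusted p = 0.773). Among lower genes they were those of the major urinary protein genes Mup3 (234.5 ± 149.7 against 6.91 ± 7.33 FPKM, adjusted p = 0.54), Mup17 and the pseudogene Mup-ps19 (adjusted p = 0.771 and 0.487), and of the carboxylesterase gene Ces3b (25.4 ± 15.2 against 2.2 ± 3.15 FPKM, adjusted p = 0.876). The urinary protein genes are close copies of each other, and reads can be split among them. Abcc4, which encodes an efflux pump for bile acids and other organic anions, stood at 38.59, 53.94 and 34.84 FPKM in the double mutant, above 5.92, 7.2 and 21.52 FPKM in the Tsc1-deleted group. Its log2 change of 1.98 (SE 0.83) did not pass (adjusted p = 1.0, and 0.359 with only these 6 libraries, with a range over its alternatives of 6.42e-05 to 1.0). Trp53 was at 7.49 ± 1.97 and 10.7 ± 4.99 FPKM, and Tsc1 at 1.08 ± 0.0555 and 0.88 ± 0.0988 FPKM, in double-mutant and Tsc1-deleted livers (SD, n = 3, adjusted p = 1.0 for both).

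Ranked against all other genes by camera at a preset correlation, fetal and liver tumour markers were placed higher in the double mutant, and drug-metabolising enzymes and cholesterol synthesis genes lower. With an estimated correlation these calls were lost (adjusted p = 0.345, 0.314 and 0.347), and fry gave unadjusted p = 0.0968, 0.21 and 0.262. Of 28 tested fetal and liver tumour markers, which are mostly silent in adult hepatocytes, 27 had a positive estimate and 8 lay above the Tsc1-deleted group without overlap. Of all genes 1372 (11.4%) did, where chance gives 5%. The median log2 change was 1.43 (camera adjusted p = 2.5e-11, adjusted p = 0.345 with an estimated correlation). Over all tested genes the median was 0.29 as deposited and 0.25 after nuclear rescaling. None of these markers passed over all genes, while 1 did adjusted over the list alone: Igf2, a fetal growth factor, at 14.98, 25.57 and 346.2 FPKM against 4.3, 0.1 and 6.72 FPKM. Cytochrome P450 and conjugation enzymes had a median log2 change of -0.86 over 30 genes and 25 negative estimates (camera adjusted p = 1.72e-17, adjusted p = 0.314 with an estimated correlation). Examples chosen after their values were seen were the drug oxidases Cyp1a2 (142.6 ± 23.3 FPKM in Tsc1-deleted against 23.7 ± 22.3 FPKM in double-mutant livers, adjusted p = 1.0) and Cyp2c54 (39.5 ± 28.5 against 3.46 ± 2.27 FPKM, adjusted p = 1.0). Cholesterol synthesis genes had 21 of 25 estimates negative, a median of -0.78 and 7 genes below without overlap, as were 382 (3.2%) of all genes (camera adjusted p = 9.62e-14, adjusted p = 0.347 with an estimated correlation). Fdps, the farnesyl diphosphate synthase gene chosen after its values were seen, stood at 74.2 ± 12.9 against 27.3 ± 17.3 FPKM.

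Camera at the preset correlation also placed other lists higher or lower than the rest of the genes. All tested genes had a median log2 change of 0.29, so positive estimates and medians above 0 partly reflect that general shift. Cholangiocyte and progenitor markers had a median log2 change of 1.15 with 16 of 16 estimates positive (camera adjusted p = 1.98e-06, adjusted p = 0.368 with an estimated correlation). The amino acid and ATF4 programme had a median of 0.84 (camera adjusted p = 7.79e-05, 0.437 as the adjusted p with an estimated correlation), and Psat1, a serine synthesis gene chosen after its values were seen, stood at 22.0 ± 8.1 against 4.56 ± 3.44 FPKM. Glycolysis and hypoxia genes had 22 of 22 positive estimates and a median of 0.77 (camera adjusted p = 0.00271, adjusted p = 0.641 with an estimated correlation). The median of p53 targets was 0.52 with 28 of 34 estimates positive (camera adjusted p = 0.019, adjusted p = 0.798 with an estimated correlation). Immediate early and heat shock genes had 19 of 22 positive estimates and a median of 0.65 (camera adjusted p = 0.0167, adjusted p = 0.73 with an estimated correlation). Wnt and perivenous hepatocyte genes had a median of -0.58 (camera adjusted p = 7.81e-09, adjusted p = 0.314 with an estimated correlation). Hepatocyte markers, 13 of 16 with a negative estimate, had a median of -0.30 and were placed lower (camera adjusted p = 7.79e-05, adjusted p = 0.387 with an estimated correlation). So were periportal hepatocyte genes, with 13 of 21 negative and a median of -0.28 (camera adjusted p = 6.6e-05, adjusted p = 0.344 with an estimated correlation). Endothelial markers (14 of 16 negative, median -0.30, camera adjusted p = 2.01e-06) and erythroid markers (5 of 6 negative, median -1.32, camera adjusted p = 0.000471) were placed lower too. With an estimated correlation their adjusted p values were 0.356 and 0.347. Male-biased liver genes had a median of -0.79 (camera adjusted p = 1.43e-12, adjusted p = 0.314 with an estimated correlation). Of their members with the highest mean, Mup20 stood at 3102 ± 263 against 277.1 ± 388 FPKM, while Gstp1 and Gstp2 had no lower level in the double mutant than the lowest Tsc1-deleted library. Xist, which is expressed from the inactive X chromosome of females, stood at 25.85, 0.01 and 28.37 FPKM in the double mutant and 24.07, 0.01 and 0.00 FPKM in the Tsc1-deleted group, and the labels give no sex. Mitochondrially encoded genes had a median of -0.77 (camera adjusted p = 6.26e-17, adjusted p = 0.314 with an estimated correlation).

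In all, 26 of 35 lists passed, 6 higher and 20 lower. With an estimated correlation none passed (lowest adjusted p = 0.314, with 4 lists at an unadjusted p under 0.05), and by fry none passed (lowest adjusted p = 0.862, with 0 lists at an unadjusted p under 0.05). For hepatocyte secreted proteins the median was 0.10 and the mean -0.06, and for Kupffer and macrophage markers they were 0.18 and -0.10, while camera placed both lists lower (adjusted p = 0.00478 and 0.00249). Stellate and fibroblast markers had a median of 0.00 and a mean of 0.01 and were also placed lower (camera adjusted p = 0.0304).

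**Figure D3:**
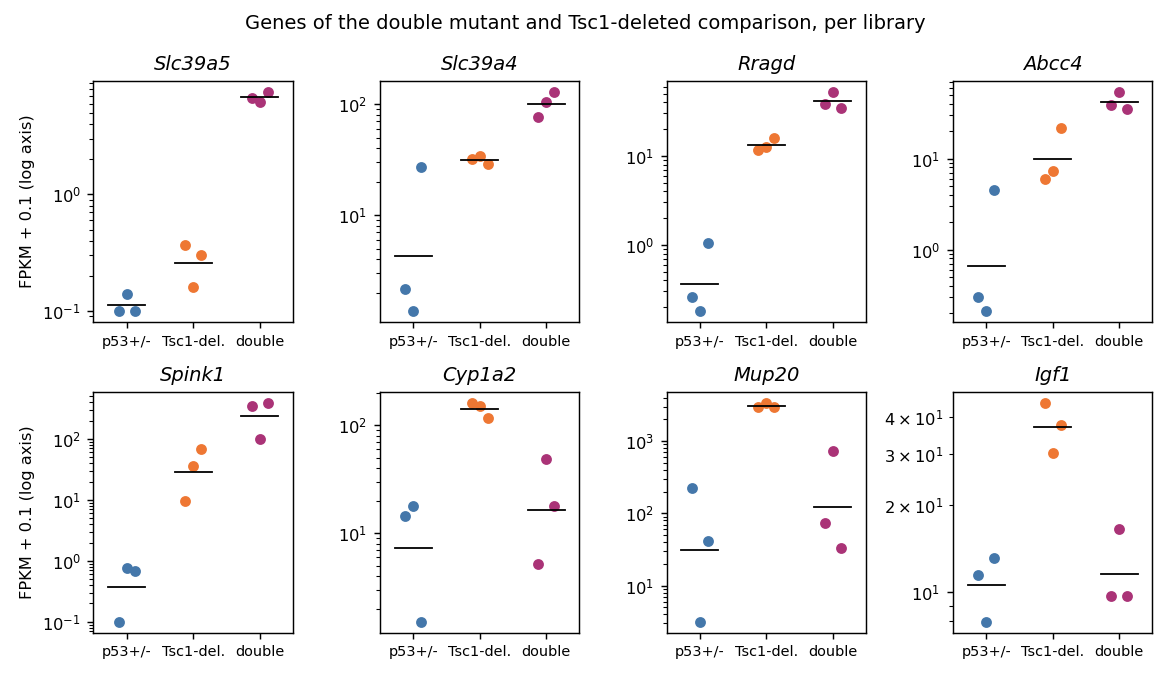
FPKM plus 0.1 on log axes for 8 genes, of which Slc39a4, Rragd, Spink1, Cyp1a2 and Igf1 were chosen after their values were seen. Each point is a library, and each line is the geometric mean of the 3 libraries of a group. Slc39a5 stands between 6.15 and 7.44 FPKM in the double mutant and at 0.27 FPKM or less elsewhere.

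**Figure D4:**
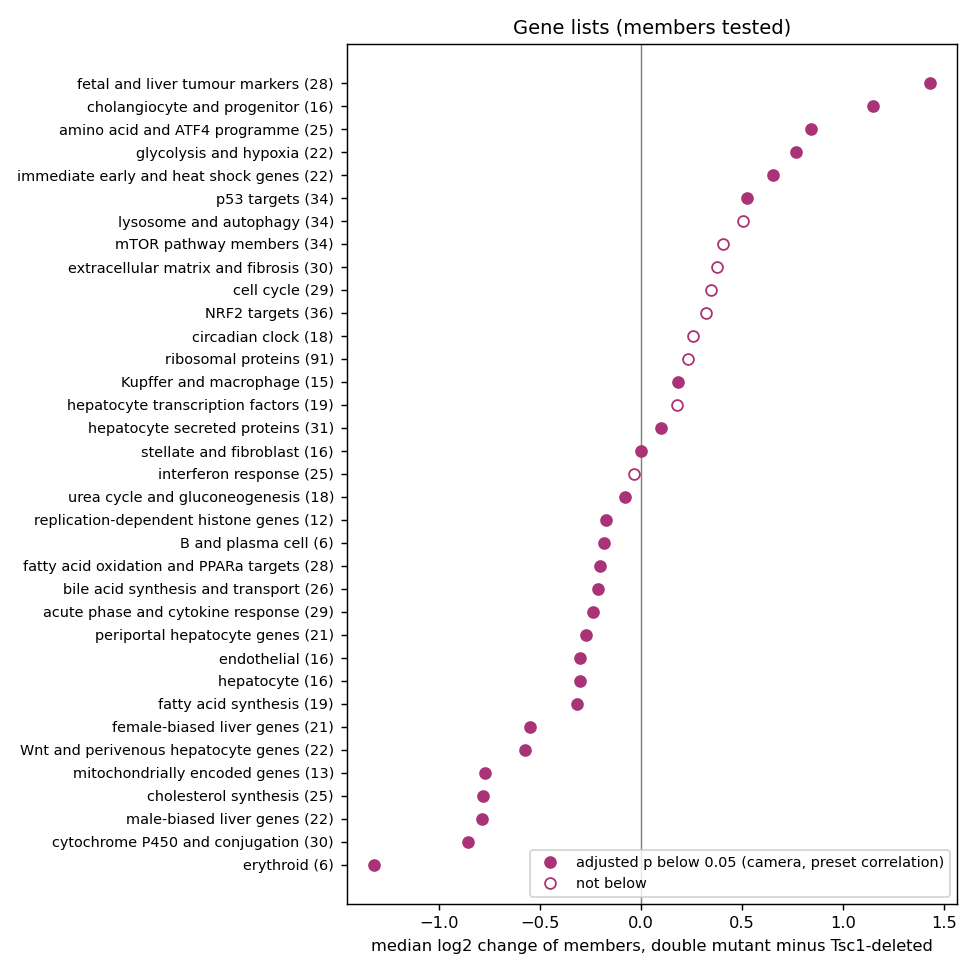
Median log2 change of the tested members of each of 35 gene lists, double mutant minus Tsc1-deleted (horizontal axis), with the number of members tested in parentheses. Filled points passed camera at a preset correlation, as 26 lists did, and none passed with an estimated correlation. Fetal and liver tumour markers had the highest median, 1.43, against 0.29 over all tested genes.

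The double mutant against the p53-heterozygous liver asks what loss of Tsc1 in hepatocytes adds on a p53-heterozygous background. Transcripts of oxidative stress, fetal, lysosomal and amino acid stress genes were placed higher in the double mutant, beyond a general shift. These 4 list calls were lost with an estimated correlation (adjusted p = 0.33, 0.471, 0.698 and 0.632). The median log2 change of all tested genes was 1.38 as deposited and 0.16 after nuclear rescaling, so a change is set against that shift here, and genes are named as holding only where they passed with both. FPKM printed in this comparison and the next are as deposited. In p53-heterozygous libraries 1 and 2, with nuclear protein-coding shares of 7.4% and 6.6%, they are low for most nuclear genes. A value of 0 there can also come from few reads. With nuclear rescaling on only the 6 libraries compared, 37 genes passed. Rragd, Slc39a5, Adnp, Spink1, Bex2, Krt23, Rnase1 and Gm44805 were among them. Abcc4, Ephx1, Gsta2, H19, Ctsl, Gabarapl1, Lamp1, Fgf21, Trib3, Cyp39a1, Ndrg1, Hsd17b13 and Spp2, which are named below as holding, were not (adjusted p from 0.0503 for Abcc4 to 0.126 for Spp2), at the same log2 changes. Rragd, a Rag GTPase that signals nutrients to mTORC1, averaged 41.6 ± 9.34 FPKM against 0.391 ± 0.473 FPKM (SD, n = 3 each), a log2 change of 4.97 (SE 0.71, limma adjusted p = 0.00174) and of 4.05 after rescaling. Abcc4 averaged 42.5 ± 10.1 against 1.59 ± 2.48 FPKM, a log2 change of 4.46 (SE 0.83, adjusted p = 0.00518) and of 3.44 after rescaling (adjusted p = 0.0203, with a range over its alternatives of 2.47e-08 to 0.0503). Slc39a5 was listed at 0, 0.04 and 0 FPKM in the p53-heterozygous group (adjusted p = 0.00115), and Adnp at 0 in all 3 libraries (adjusted p = 0.000612). Summed with Gm20716, Adnp stood at 0.54, 0.46 and 8.39 FPKM there and at 15.23, 9.38 and 7.93 FPKM in the double mutant, so the groups overlapped.

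By list, 31 of 36 NRF2 targets, genes of the oxidative stress response, rose over all genes and 33 rose adjusted over the list alone (camera adjusted p = 1.61e-14, adjusted p = 0.33 with an estimated correlation). After nuclear rescaling 8 members rose. The epoxide hydrolase gene Ephx1 (464 ± 60.6 against 10.01 ± 7.49 FPKM) and the glutathione transferase gene Gsta2 (227.7 ± 119.6 against 1.95 ± 0.163 FPKM) held, while their relatives Gsta1 and Gstm3 did not (adjusted p = 0.138 and 0.182 after rescaling). Of 28 fetal and liver tumour markers, 21 rose over all genes and 21 adjusted over the list alone, 9 after rescaling (camera adjusted p = 2.79e-06, adjusted p = 0.471 with an estimated correlation). H19, an imprinted fetal RNA (143.9, 700.7 and 891.4 FPKM against 0.8, 2.01 and 1.21 FPKM), Spink1, a trypsin inhibitor (281 ± 157 against 0.41 ± 0.358 FPKM), and Bex2, listed at 0 in the p53-heterozygous group and at 37.55, 33.98 and 83.43 FPKM in the double mutant, held. Tff3, a secreted mucosal peptide, did not (adjusted p = 0.0054 as deposited and 0.18 after rescaling, with a range over its alternatives of 4.48e-07 to 0.285).

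Among 34 lysosome and autophagy genes 21 rose over all genes and 30 adjusted over the list alone, 6 after rescaling (camera adjusted p = 0.000557, adjusted p = 0.698 with an estimated correlation). Of these the protease gene Ctsl (257 ± 40.7 against 7.58 ± 9 FPKM), the autophagy gene Gabarapl1 (321.2 ± 109.9 against 10.8 ± 10.2 FPKM) and the lysosomal membrane gene Lamp1 (610.2 ± 184 against 42.2 ± 60.7 FPKM) held, though Lamp1 did not pass without double-mutant library 2 (adjusted p = 0.0534). In the amino acid and ATF4 programme 15 of 25 rose over all genes and 20 adjusted over the list alone, 2 after rescaling (camera adjusted p = 0.00187, adjusted p = 0.632 with an estimated correlation), among them the hormone gene Fgf21 (50.71, 22.63 and 7.73 FPKM against 0, 0 and 0.22 FPKM) and the stress kinase homologue Trib3 (43.3 ± 37.1 against 1.02 ± 1 FPKM), which held. Of 16 cholangiocyte and progenitor markers 13 rose over all genes and 14 adjusted over the list alone, 1 after rescaling (camera adjusted p = 0.00643, adjusted p = 0.693 with an estimated correlation), and the keratin gene Krt23 (8.41 ± 3.43 against 0.114 ± 0.197 FPKM) held while the adhesion gene Epcam did not (adjusted p = 0.0787 after rescaling). Of 26 bile acid genes 23 rose over all genes and 26 adjusted over the list alone, 4 after rescaling (camera adjusted p = 3.02e-08, adjusted p = 0.189 with an estimated correlation), and the oxysterol hydroxylase gene Cyp39a1 held with Abcc4, while the export pump gene Abcc3 did not (adjusted p = 0.0534 after rescaling). With p53-heterozygous library 3 out and nuclear rescaling the bile acid list did not pass (median -0.01, camera adjusted p = 0.407). The cholangiocyte (median 2.46, camera adjusted p = 1.94e-06), fetal (2.42, 5.29e-06), NRF2 (1.63, 4.94e-05), lysosome (1.15, 0.00104) and ATF4 lists (1.42, 0.00146) did, with 15, 16, 18, 18 and 9 members that rose. Of 34 p53 targets 17 rose over all genes and 19 adjusted over the list alone, but the list did not pass as deposited (camera adjusted p = 0.0518, adjusted p = 0.822 with an estimated correlation). It passed after rescaling (median 0.56, camera adjusted p = 0.00395) and with library 3 of the p53-heterozygous group out too (0.97, 0.00473), yet neither the cell cycle inhibitor gene Cdkn1a nor Trp53inp1 passed after rescaling (adjusted p = 0.092 and 0.0523). Glycolysis and hypoxia genes did not pass as a list as deposited (camera adjusted p = 0.181, adjusted p = 0.828 with an estimated correlation). They passed after rescaling (median 0.46, camera adjusted p = 0.0377) and with that library out too (0.78, 0.0151), and of the 10 that rose over all genes (15 adjusted over the list alone) the hypoxia-responsive gene Ndrg1 held.

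Hepatocyte genes were higher in the double mutant as deposited: 16 of 16 hepatocyte markers rose (camera adjusted p = 3.63e-08, adjusted p = 0.347 with an estimated correlation), and 28 of 31 secreted proteins did, 30 adjusted over the list alone (camera adjusted p = 2.05e-16, adjusted p = 0.33 with an estimated correlation). No gene of these lists passed after nuclear rescaling, among them Ahsg, which encodes the plasma protein fetuin-A (7593 ± 2023 against 193.2 ± 104 FPKM, adjusted p = 0.18 after rescaling), and the urea cycle gene Cps1 (adjusted p = 0.247). As lists, the secreted proteins still passed after nuclear rescaling (median 1.75, camera adjusted p = 0.0108), while the hepatocyte markers did not (1.23, 0.0823). With p53-heterozygous library 3 out and nuclear rescaling the hepatocyte markers were placed lower (median -0.25, camera adjusted p = 0.0428). Markers of several other cell types were placed lower after nuclear rescaling: stellate cells (median -1.38, camera adjusted p = 6.93e-07), endothelium (-0.87, 0.000458), Kupffer cells (-0.88, 0.00546), B cells (-1.31, 0.00261) and erythroid cells (-4.75, 9.52e-05). Cholangiocyte markers were placed higher (median 1.74, camera adjusted p = 1.73e-05). With library 3 out too the Kupffer median was -0.04, while those of stellate, B and erythroid cells were -1.13, -1.78 and -7.06. As deposited the 5 lower lists did not pass with an estimated correlation (adjusted p = 0.471, 0.471, 0.388, 0.471 and 0.0602). Of 30 P450 and conjugation genes 16 rose over all genes and 18 adjusted over the list alone (camera adjusted p = 0.0119, adjusted p = 0.693 with an estimated correlation). That list did not pass after rescaling (median 0.51, camera adjusted p = 0.384), and with p53-heterozygous library 3 out too it was placed lower (median -0.56, camera adjusted p = 0.000866). Other large rises of the rule that held were Rnase1, a secreted ribonuclease, Hsd17b13, a lipid droplet enzyme, Spp2, a secreted phosphoprotein, and Gm44805, which overlaps Apoc2 and Apoc4, while Apom, an apolipoprotein gene, and Gm3776, a copy close to Gsta1, did not (adjusted p = 0.0514 and 0.114 after rescaling). Mitochondrially encoded genes fell, 11 of 13 over all genes and 13 adjusted over the list alone, with a median log2 change of -2.11 (camera adjusted p = 3.59e-68, adjusted p = 0.0532 with an estimated correlation). After nuclear rescaling 1 of them passed, at a list median of -4.55 (camera adjusted p = 7.16e-11). The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 also fell, by 4.18 and 3.83 on the log2 scale (SE 0.91 and 0.91, adjusted p = 0.00892 and 0.0112), with the mitochondrial transfer RNA genes mt-Ts2, mt-Th and mt-Tl2, the ribosomal repeat gene AY036118, and Gm47287, Gm47305 and Gm47299, which overlap genes of the 7SL RNA. Mup3 was the only fall of the 10 in the rule from a nuclear protein-coding gene (6.91 ± 7.33 against 143.3 ± 199 FPKM, adjusted p = 0.0327), and it did not pass after rescaling (adjusted p = 0.0672) or without p53-heterozygous library 1 or any 1 double-mutant library (adjusted p = 0.183, 0.123, 0.0691 and 0.11). The call for mt-Rnr1 ended without double-mutant library 2 (adjusted p = 0.0584), and that for mt-Rnr2 without double-mutant library 1 or 2 (adjusted p = 0.0546 and 0.0587). Trp53 and Tsc1, with log2 changes of 1.32 and 0.55 as deposited and of -0.23 and -0.40 after rescaling, did not pass (adjusted p = 0.199 and 0.179 as deposited).

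Over all genes 3892 passed, 3838 higher and 54 lower, and 26 of 35 lists did, 15 higher and 11 lower. None passed with an estimated correlation (lowest adjusted p = 0.0532, with 5 lists at an unadjusted p under 0.05), and 21 did by fry, 20 higher and 1 lower. Fry asks whether a list moved at all, so under a shift of all genes it does not test the camera calls. Of the lower lists, 9 had a median above 0, since camera ranks a list against the shift of all genes. After nuclear rescaling 447 genes passed, 258 higher and 189 lower, and 278 of them were among the 3892. With only the 6 libraries compared, as deposited, 1127 genes passed, 1103 higher and 24 lower. Leaving out a p53-heterozygous library gave 787, 868 and 11295 genes, leaving out a double-mutant library 485, 322 and 773, and leaving out Tsc1-deleted library 1 or 2 gave 2232 and 2398.

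The Tsc1-deleted against the p53-heterozygous liver sets the single mutants side by side. The oxidative stress response and Rragd were higher in the Tsc1-deleted liver. Of 36 NRF2 targets 25 rose over all genes and 30 adjusted over the list alone (camera adjusted p = 1.74e-14, adjusted p = 0.153 with an estimated correlation), among them Gsta2 (229.6 ± 117 against 1.95 ± 0.163 FPKM, log2 change 6.17, SE 0.85, limma adjusted p = 0.00469), Gstm3, Gsta1 and Ephx1 (383.8 ± 37.3 against 10.01 ± 7.49 FPKM). The list passed after nuclear rescaling with a median of 1.52 (camera adjusted p = 4.48e-11), though no single member did. Rragd averaged 13.4 ± 2.3 against 0.391 ± 0.473 FPKM, a log2 change of 3.41 (SE 0.71, adjusted p = 0.0101) and of 2.53 after rescaling (adjusted p = 0.0192, with a range over its alternatives of 9.02e-10 to 0.11). Defb1, which encodes an antimicrobial peptide, was listed at 0 in the p53-heterozygous libraries and at 33.0, 65.41 and 90.14 FPKM in the Tsc1-deleted ones (adjusted p = 0.00309, and 0.000756 after rescaling, with a range over its alternatives of 1.32e-09 to 0.0527). The call for Rragd ended without any 1 of the Tsc1-deleted libraries (adjusted p = 0.0718, 0.0543 and 0.0563), and that for Defb1 without library 2 or 3 of that group (adjusted p = 0.0502 and 0.0527). Abcc4 averaged 11.5 ± 8.66 against 1.59 ± 2.48 FPKM and did not pass (adjusted p = 0.057), and nor did Trp53 or Tsc1 (log2 changes of 1.72 and 0.40 as deposited and of 0.18 and -0.52 after rescaling, adjusted p = 0.167 and 0.361 as deposited).

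Hepatocyte functions were higher in the Tsc1-deleted liver as deposited. Of 30 P450 and conjugation genes 24 rose over all genes and 29 adjusted over the list alone (camera adjusted p = 1.48e-14, adjusted p = 0.153 with an estimated correlation), with the coumarin hydroxylase gene Cyp2a5 at 1099 ± 364 against 24.8 ± 21.6 FPKM. Of 26 bile acid genes 21 rose and 26 did adjusted over the list alone (camera adjusted p = 5e-14, adjusted p = 0.109 with an estimated correlation), with the sterol hydroxylase gene Cyp8b1 at 64.4 ± 14.9 against 1.04 ± 0.742 FPKM and the bile salt uptake gene Slc10a1 at 87.3 ± 63.8 against 2.18 ± 1.06 FPKM. Of 25 cholesterol synthesis genes 19 rose and 25 did adjusted over the list alone (camera adjusted p = 4.31e-10, adjusted p = 0.379 with an estimated correlation), with the sterol desaturase gene Sc5d at 115.2 ± 38.8 against 5.04 ± 1.82 FPKM. All 16 hepatocyte markers rose (camera adjusted p = 1.47e-14, adjusted p = 0.127 with an estimated correlation), as did 30 of 31 secreted proteins, 31 adjusted over the list alone (camera adjusted p = 3.23e-25, adjusted p = 0.109 with an estimated correlation), with the thyroxine carrier gene Ttr at 5485 ± 2265 against 185.3 ± 92.4 FPKM, Ahsg at 5842 ± 1797 against 193.2 ± 104 FPKM, and the urea cycle genes Ass1 and Cps1 higher too. Of 22 male-biased genes 9 rose, 16 adjusted over the list alone (camera adjusted p = 0.00538, adjusted p = 0.58 with an estimated correlation), led by Mup20 (3102 ± 263 against 90.8 ± 120.3 FPKM). Mup-ps19 was listed at 0 in the p53-heterozygous libraries and at 758.9, 912.1 and 957.6 FPKM in the Tsc1-deleted ones (adjusted p = 0.00687). The other rises of the rule were Ly6d, a surface protein gene, Aqp8, a water channel gene, Gm44805 and Gm3776. Mitochondrially encoded genes were placed lower as a list, with a median of -1.34 and no member that passed (camera adjusted p = 5.96e-38, adjusted p = 0.109 with an estimated correlation). After nuclear rescaling on 9 libraries the P450 (median 1.43, camera adjusted p = 1.5e-06), bile acid (1.36, 1.38e-07), hepatocyte (1.75, 6.87e-05), secreted protein (1.64, 3e-06) and male-biased (0.74, 0.032) lists still passed. With p53-heterozygous library 3 out and nuclear rescaling, the P450 (median 0.07, camera adjusted p = 0.999), bile acid (0.48, 0.308), hepatocyte (0.28, 0.977), secreted protein (0.12, 0.556) and male-biased (0.32, 0.499) lists did not pass. The NRF2 (1.27, 3.35e-06) and cholesterol lists (0.69, 0.0364) did. Among other cell types, nuclear rescaling placed stellate (median -1.18, camera adjusted p = 3.2e-05), erythroid (-3.39, 0.00367) and B cell markers (-1.22, 0.0373) lower. Cholangiocyte markers were placed higher (0.50, 0.00518), and Kupffer (-0.81, 0.0675) and endothelial markers (-0.31, 0.153) did not pass. Among the 11 single genes that fell were mt-Rnr1 and mt-Rnr2 (adjusted p = 0.0261 and 0.0294), the transfer RNA genes mt-Tl2, mt-Tv and mt-Tf, Snora68, Gm47299, Gm22513 and Gm6058. Of 6 erythroid markers 1 also fell over all genes.

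Over all genes 1470 passed, 1459 higher and 11 lower, and the median log2 change of all tested genes was 1.07 as deposited and -0.10 after nuclear rescaling. With only the 6 libraries compared, as deposited, 20 genes passed, all higher. The fit on 9 libraries shares 1 spread per gene with the double mutant, which is not part of this comparison. With rescaling 21 genes passed, 10 higher and 11 lower, 12 of them shared with the 1470. Cyp2a5, Cyp8b1, Slc10a1, Sc5d, Ttr, Ahsg, Ass1, Cps1, Mup20, Gsta2, Gsta1, Gstm3, Ephx1, Ly6d, Aqp8 and Mup-ps19 did not pass with it. Of 20 named changes checked in this comparison, 14 calls ended without Tsc1-deleted library 1, and all 20 ended without library 2 and without library 3. Leaving out a Tsc1-deleted library gave 9, 1 and 1 genes, leaving out a p53-heterozygous library 587, 612 and 10820, and leaving out a double-mutant library 810, 880 and 774. Of the 35 lists 21 passed, 15 higher and 6 lower, of which 4 had a median above 0. None passed with an estimated correlation (lowest adjusted p = 0.109, with 10 lists at an unadjusted p under 0.05), and 15 did by fry, all higher, which under the shift of all genes does not test the camera calls either.

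Against both single mutants, 2 genes were higher in the double mutant, Slc39a5 and Adnp, and none was lower. Summed with the overlapping Gm20716, Adnp was not above either single mutant without overlap (15.23, 9.38 and 7.93 FPKM against up to 8.39 in the p53-heterozygous and up to 12.16 in the Tsc1-deleted group). In 100 simulations in which the double-mutant libraries were shared and no gene differed, the mean overlap was 0, and independent lists of these sizes would share 0.639 rises. Hardly any gene can be called where none differs, while 3892 passed here against the p53-heterozygous group. The simulations therefore cannot show what overlap chance gives. The real comparisons share the double-mutant libraries, so the value for independent lists cannot either. At an unadjusted p under 0.05 in both comparisons the count was 183. It was 4 without p53-heterozygous library 3 and 4 without double-mutant library 2, 1 without Tsc1-deleted library 1, and 0 without Tsc1-deleted library 2 (limma, 71 at an unadjusted p under 0.05).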

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

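The tests with nuclear rescaling, the same total of FPKM, p53-heterozygous libraries 1 and 2 out, library 3 of that group out with nuclear rescaling, the Xist covariate, and the 6 libraries rescaled or with 1 left out were chosen after the results were seen. Below, D-T, D-P and T-P stand for double mutant minus Tsc1-deleted, double mutant minus p53-heterozygous, and Tsc1-deleted minus p53-heterozygous, and "both" for genes changed in the double mutant against both single mutants. The counts to compare are 3, 3892, 1470 and 2 genes, and 26, 26 and 21 lists. Where no reason is given, the cause was not tested.

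A pseudocount of 0.1 gave 1 gene for both. With no filter, which tests more genes, D-T gave 1 gene (952 at an unadjusted p under 0.05), D-P 1142, T-P 599 and both 1. A filter at 5 FPKM gave 16 lists for D-P and 1 gene for both. Median-ratio rescaling gave 787 genes for D-P (417 higher, 370 lower), 17 lists for D-P and 269 genes for T-P (138 higher, 131 lower). Quantile normalization gave 16 lists for D-T, 860 genes for D-P (398 higher, 462 lower) and 100 genes for T-P (36 higher, 64 lower). Limma without trend and robust steps gave 0 genes for D-T (215 at an unadjusted p under 0.05) and 0 for both (122). Array weights, whose estimation stopped before converging, gave 6987, 11680 and 11429 genes for D-T, D-P and T-P, 6085 for both and 17 lists for D-P. Only the 6 libraries compared gave 1127 genes for D-P and 20 for T-P. A replicate block gave 35, 5974, 2277 and 28 genes for D-T, D-P, T-P and both. The labels do not say that equal numbers pair libraries, and the values did not decide it. Deviations from the group means correlated at -0.20 to 0.32 over 9 pairs with the same number, and 4 pairs matched best with their own number. So few pairs cannot show whether libraries are paired. Camera with an estimated correlation gave 0, 0 and 0 lists for D-T, D-P and T-P (4, 5 and 10 at an unadjusted p under 0.05), and fry 0 lists for D-T (0 at an unadjusted p under 0.05).

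The same total of FPKM gave 8244 genes for D-P. Nuclear rescaling gave 447 genes for D-P and 21 for T-P. Without p53-heterozygous libraries 1 and 2, where the lone library left was assumed to vary like the others, D-P gave 2212 genes (1265 higher, 947 lower) and T-P 2600 (1179 higher, 1421 lower). Library 3 out with nuclear rescaling gave 13 lists for T-P. The Xist covariate gave 1, 1740, 909 and 1 genes for D-T, D-P, T-P and both. The 6 libraries with nuclear rescaling gave 37 genes and 17 lists for D-P and 7 genes for T-P.

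Leaving out 1 of the 9 libraries gave 0 to 6 genes for D-T, 322 to 11295 for D-P, 1 to 10820 for T-P and 0 to 4 for both, and 22 to 28, 19 to 26 and 15 to 24 lists. Within only the 6 libraries, D-T gave 1133 genes without Tsc1-deleted library 3 (1035 higher, 98 lower), 13 without double-mutant library 2, 6 without Tsc1-deleted library 1 or double-mutant library 3, and 5 without Tsc1-deleted library 2.

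Trp53 and Tsc1, which passed in none of these comparisons as reported, changed sign. Their log2 changes as reported were -0.40 and 0.15 in D-T, 1.32 and 0.55 in D-P, and 1.72 and 0.40 in T-P. Trp53 in D-T was 0.02 with array weights. Tsc1 in D-T was -0.04 with median-ratio rescaling and -0.08 with quantile normalization. In D-P Trp53 was -0.33 and -0.34 with those, -0.23 with nuclear rescaling on 9 or 6 libraries and -0.98 without libraries 1 and 2. Tsc1 in D-P was -0.43, -0.57 and -0.40 with the same 3 rescalings and -0.53 with library 3 out and nuclear rescaling. In T-P Trp53 was -0.58 without libraries 1 and 2. Tsc1 in T-P was -0.40, -0.49 and -0.52 with the 3 rescalings, -0.09 without libraries 1 and 2 and -0.65 with library 3 out and nuclear rescaling. Of 2244 values of 84 named changes under the alternatives, 1881 kept direction and side of the threshold, 274 were no longer past it, 69 were newly past it and 20 changed sign. A planned conversion to TPM was not run. In the simulated data few genes shifted by 1 or 2 were recovered with 9 libraries (3% for a shift of 2 in D-T), so a gene that did not pass is not shown to be equal.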

Other observations

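The tests of the scaling, of overlapping gene models and of Xist in this part were chosen after the results were seen, and the splits of the libraries were planned.

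Within the double mutant, fetal and tumour transcripts were uneven. Afp, the fetal serum protein gene, stood at 16.96, 1.07 and 1965 FPKM in libraries 1 to 3, Gpc3, a cell surface proteoglycan gene, at 80.8, 0.76 and 100.6 FPKM, and Igf2 at 14.98, 25.57 and 346.2 FPKM. These genes were chosen after their values were seen. The hemoglobin gene Hbb-bs stood at 232.8, 724.1 and 27.2 FPKM in the p53-heterozygous libraries, 79.6, 138.8 and 50.4 in the Tsc1-deleted and 7.52, 41.0 and 105.3 in the double-mutant ones.

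Nearly all genes that passed against the p53-heterozygous group were higher in the other group. If this came from mitochondrial transcripts taking most reads in p53-heterozygous libraries 1 and 2, equal nuclear totals should even out the directions. With nuclear rescaling 57.7% of the genes that passed for the double mutant were higher, but equal totals centre the genes whatever the cause, so this does not decide it. With library 3 out too, 2165 of 2893 were higher, and without libraries 1 and 2, as deposited, 1265 of 2212 were. Without library 3, 99.3% were higher, so its tissue makeup was not needed for the pattern. Libraries 1 and 2, then alone in their group, had nuclear protein-coding shares of 7.4% and 6.6%. A high percent was to be foreseen from those shares, so this cannot show what library 3 adds. Hepatocyte markers had a median log2 change of 1.23 after rescaling, which did not pass (camera adjusted p = 0.0823), and of -0.249 with library 3 out, when camera placed them lower (adjusted p = 0.0428), so few hepatocyte transcripts in that library alone could account for that median. What made the mitochondrial share high was not tested, and genotype stays open. It was 25.5% in p53-heterozygous library 3 and 8.0% to 11.9% in the double mutant, which is also p53-heterozygous, so heterozygosity alone does not track it. Genes neither mitochondrial nor nuclear protein-coding held 24.5% and 37.5% in libraries 1 and 2, against 4.7% to 12.7% elsewhere.

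For the 3 genes called between the double mutant and the Tsc1-deleted group, values were summed over overlapping or copied gene models. Adnp summed with Gm20716 gave groups that overlap, with the lowest double-mutant library 4.23 FPKM under the highest Tsc1-deleted one (a gap of -4.23), so reads assigned to another model could account for its call. For Hist2h2aa1, values were summed over H2A genes and the overlapping Gm20634, Gm20633 and Gm47313. The lowest Tsc1-deleted library then lay 31.28 FPKM above the highest double-mutant one. For Slc39a5 and its neighbours the double-mutant libraries stayed above by 3.06 FPKM. FPKM is divided by gene length, so reads moved between models of different length change such a sum. Neither gap can therefore exclude moved reads. Moved reads stay open for Hist2h2aa1 and Slc39a5, and so does a biological source as a hypothesis.

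Camera placed male-biased liver genes lower in the double mutant than in the Tsc1-deleted group, a call lost with an estimated correlation (adjusted p = 0.314), and none of the 22 members passed. Xist was above 20 FPKM in 2 double-mutant libraries and 1 Tsc1-deleted library. With the Xist level as a covariate the median of the list was -0.275 against -0.79 without it, between the values set for either outcome, and camera at the preset correlation still placed it lower (adjusted p = 3.82e-06). More females should raise female-biased genes, yet 16 of 21 had a negative estimate, with a median of -0.55 (camera adjusted p = 1.08e-05, adjusted p = 0.347 with an estimated correlation) and of -0.98 with the covariate (camera adjusted p = 1.6e-16). That goes against more females as the only difference, though another change can lower both lists. More females in the double mutant cannot be told apart here from an effect of genotype, since Xist and group are partly confounded in 6 libraries.

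With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For the double mutant minus Tsc1-deleted, 2 of 10 splits gave at least as many genes (3 real, 5 the highest other), 1 of 10 as many lists (26 and 23), and 3 of 10 as many genes without overlap (1754 and 3814, where chance gives 10%). Every other split in this comparison still called 15 to 23 lists. The split with 3814 set Tsc1-deleted libraries 1 and 2 with double-mutant library 2 against the rest. Their factors in the median-ratio rescaling were 1.361, 1.294 and 1.905, the lowest of the 6 libraries, so the split follows the scale of the libraries as deposited. For the double mutant minus p53-heterozygous the counts were 1 of 10 for genes (3892 and 555) and 3 of 10 for lists (26 and 27). For the Tsc1-deleted minus p53-heterozygous they were 2 of 10 for genes (1470 and 5347) and 6 of 10 for lists (21 and 22). The split with 5347 set p53-heterozygous libraries 1 and 2 with Tsc1-deleted library 2 against the rest. These also had the lowest median-ratio factors of their 6 libraries (0.145, 0.133 and 1.294). Whether the factors account for the counts of these splits was not tested. For genes changed against both single mutants, 13 of 100 drawn assignments of the 9 libraries gave at least 2 genes (highest other 4671), so chance is not excluded.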
